A study of Homo sapiens with 40 samples.

How the data were processed

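RNA levels were measured in 4 human ovarian carcinoma cell lines grown as monolayers (2D) or as spheroids in low-attachment plates (3D). Per the labels, spheroids, but not monolayers, were dissociated with collagenase and a trypsin substitute before RNA was extracted, so the culture form and this step cannot be told apart. Libraries were made from total RNA after removal of ribosomal RNA. The values are gene-level TPM as deposited by the authors, in a table of libraries by gene symbols. The processing notes of the authors name DRAGEN, FastQC, limma 3.66 and the GRCh38/hg38 genome build. The role of these tools in alignment and quantification is not given in the sources used here, and neither are the versions of the others. The sum of a library over the genes listed was 974670 to 986990 TPM. TPM keeps no read counts, so the depth per library was unknown and no counting interval was computed.

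Of the 42 libraries in the table, 37 were matched to samples through the names that the labels give, and the 5 that could not be matched were not used. Of the 40 samples, 3 Kuramochi spheroid samples (replicates 5 to 7) had no values and were not analysed here. Lines, culture forms and days were taken from the sample titles. For 6 samples the cell line field named another line than the title. Of these, 3 had values, all OVCAR4 spheroids by their titles, and each of them correlated best with OVCAR4 monolayers. A single OVCAR4 spheroid library, replicate 6, had no day in its label and entered no main comparison. It was matched through the library name in its description, whose number differs from that of the title. Its name in the table also carries a mark that reads as a degree of confluence, which the title lacks. The groups held 4 COV362, 4 Kuramochi, 2 OVCAR4 and 4 OVSAHO monolayer libraries and 5, 4, 3 and 4 spheroid libraries of day 7. No pair of libraries held identical values.

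The table held 27581 gene symbols, of which 27531 were matched to a single gene of the GENCODE annotation of GRCh38 and 50 were not. Positions, gene types, transcript lengths and GC content were taken from that annotation. Each library was divided by a median-of-ratios factor computed in R 4.3.3 over the 10148 genes with a TPM of 1 or more in each library, with the geometric mean of the factors set to 1. The factors ranged from 0.651 to 1.32. The result is called scaled TPM. Values were then taken as log2(scaled TPM + 1). Genes with a TPM of 1 or more in at least 3 libraries were tested, 16611 in the culture comparison and 16652 in the day comparison.

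The 30 monolayer and day 7 spheroid libraries were fitted with limma 3.58.1, with a mean for each line and culture form (22 residual degrees of freedom), moderated variances with an intensity trend and Benjamini-Hochberg adjustment at 0.05. From this fit came the change in each line, the unweighted mean of the 4 changes, a moderated F test of the difference between the changes, and a moderated F test between the monolayers of the lines. All tests were two-sided where a direction applies. Days were compared among 22 spheroid libraries in an additive limma fit of line and day (16 residual degrees of freedom), in which single libraries of different lines stand as replicates. Of these degrees of freedom, 12 came from the spread between day 7 libraries of the same line. Values are given as mean ± SD of scaled TPM over the n libraries of a group. Tables were handled with jsonlite 2.0.0, the R package data.table (version 1.17.8) and pandas 2.3.3 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

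The 39 gene lists were written from general knowledge before the data were examined, as were the comparisons, the tests and the rule for naming genes. Lists with at least 3 tested genes were tested with camera in limma at a preset correlation of 0.01 between genes, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The difference between lines in a list was tested with a limma F test on the mean of the list's centred log2 values per library. Listed symbols that were not in the table, such as RIGI, BMAL1 and PIFO, were left out. Several lists share genes or biology, so their results are not independent.

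Genes were named by a rule that asked for an approved-style symbol, no clone, pseudogene or small RNA name, and a mean TPM of 2 or more in the higher group. It took the 12 largest rises and 12 largest falls in the mean of the lines among genes past the threshold with the same sign in all 4 lines, and the 5 largest rises and falls in each line. It also took the 8 smallest p-values among genes called in opposite directions in different lines, and the 4 genes per line that stood out most in monolayers. For the days it took the 8 largest rises and falls, or the 5 smallest p-values where fewer than 3 genes passed. Up to 4 members with the smallest adjusted p were taken from each list, and PAX8, WT1, MUC16, MKI67, CA9 and FOS were fixed beforehand.

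The fits were tested on simulated data in which 200 genes were changed by a log2 value of 0.5, 1 or 2. In the mean of the lines 83.6, 98.5 and 100% of these were recovered with 9 false calls, in OVCAR4 alone 19.4, 71.6 and 97.0% with 11, and for day 3 against day 7 38.8, 97.0 and 98.5% with 7. Alternatives tried were TPM as deposited, quantile normalization, a pseudocount of 0.1, no filter, a filter at a TPM of 5, a separate fit of each line, limma's array weights, all spheroid libraries whatever their day, the line from the cell line field, the fit without the libraries whose labels conflict, the replicate number as a block, cell means of line and day, and leaving out each library in turn. Further fits, chosen after seeing the data, separated the day 7 libraries by whether their titles ended in 7days, and left out replicates 1 and 4 or 2 and 3 of the COV362 monolayers, which stood in 2 pairs. Reassignments of the labels within lines, 100 at most for each result with a seed of 1, gave the number of calls that other splits of the same libraries produce.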

Results

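Transcript levels were measured by sequencing ribosomal-RNA-depleted total RNA from 4 established human cell lines of high-grade serous ovarian carcinoma, COV362, Kuramochi, OVCAR4 and OVSAHO, each grown either as an adherent monolayer (2D) or as spheroids in low-attachment plates (3D). The question, per the series text, was how the molecular state of these lines differs between the culture forms. The main comparison used 14 monolayer libraries (4 of COV362, 4 of Kuramochi, 2 of OVCAR4 and 4 of OVSAHO) and 16 spheroid libraries of day 7 (5, 4, 3 and 4). In addition there was 1 spheroid library of day 3 for COV362, Kuramochi and OVSAHO each, 1 of day 10 for Kuramochi, OVCAR4 and OVSAHO each, and 1 OVCAR4 spheroid library whose day was not given. The labels do not say that the libraries of a group came from separate cultures, so every p-value below measures only the spread between these libraries. Levels are in TPM, transcripts scaled to a fixed total per library, a unit that does not keep the read depth, so the depth of each library was unknown and no counting error could be attached to a value. Each of the 37 libraries had 12062 to 14758 genes at a TPM of 1 or more. Small RNAs took 18.8 to 56.8% of the TPM and mitochondrially encoded transcripts 2.30 to 23.3%, and replicate 1 of the OVCAR4 day 7 spheroids held both the lowest small RNA share and the highest mitochondrial share.

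The cell line accounted for most of the variation. It explained 73.9% of the variance over all tested genes in the 30 libraries, the culture form another 5.67%, the difference between lines in the culture effect 6.82%, and the spread within groups 13.7%. The first 3 principal components (29.1, 25.9 and 19.6% of the variance) separated the lines, while component 4, with 6.94% of the variance, separated monolayers from spheroids, and the culture form explained 70.1% of its scores. All 37 libraries correlated best with the monolayers of the line named in their title, including 3 whose cell line field named another line.

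**Figure D1:**
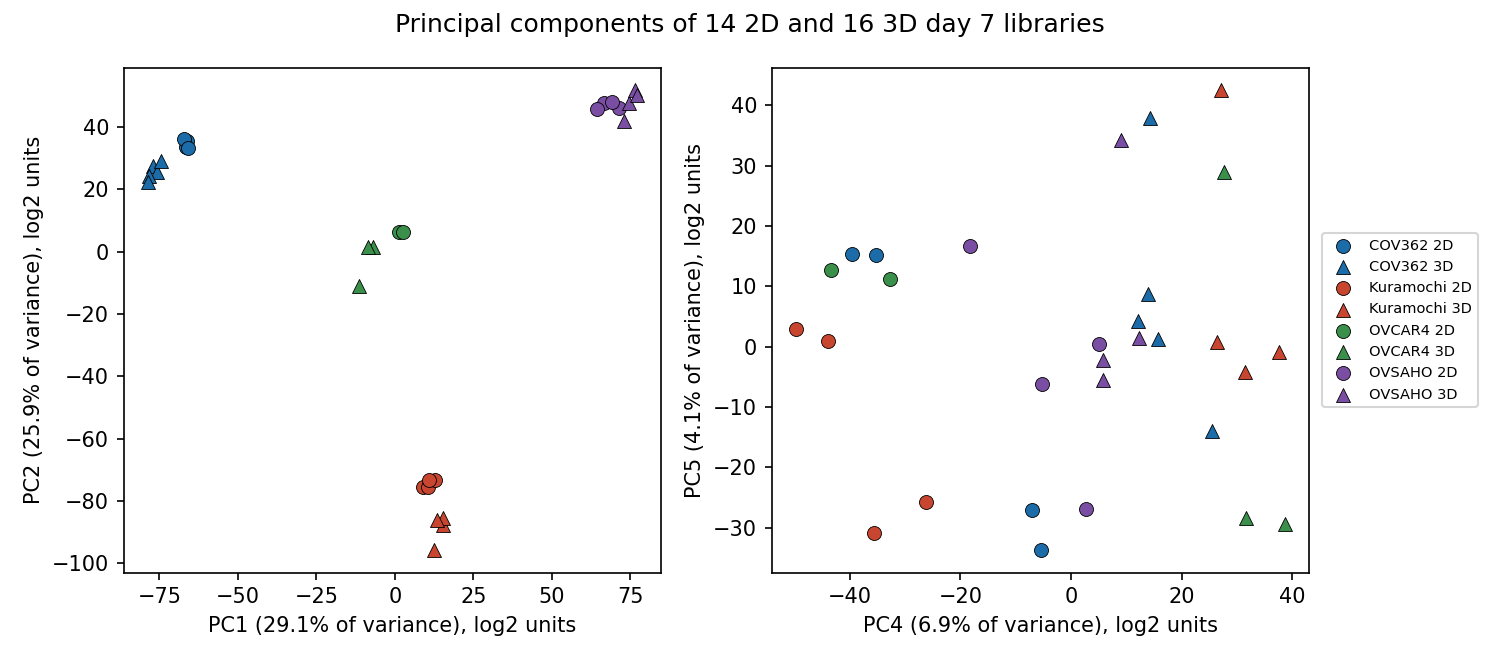
Principal component scores of the 30 monolayer and day 7 spheroid libraries on log2(scaled TPM + 1), each point a library, coloured by line and shaped by culture form, with the percent of variance on each axis. The first components, with 29.1 and 25.9% of the variance, separated the 4 lines, and component 4, with 6.94%, separated spheroids from monolayers.

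Averaged over the 4 lines, the largest fall from monolayers to spheroids of day 7 was that of CCN2 (chromosome 6, 131948176 to 131951373), a secreted matricellular protein gene and a standard target of the transcriptional regulator YAP, at a log2 change of -3.30 (SE 0.29, limma adjusted p = 1.6e-09). Its scaled TPM was 111 ± 17.3 (SD, n = 4) in COV362 monolayers against 11 ± 9.08 (SD, n = 5) in spheroids, and 103 ± 67.2 (SD, n = 4) against 2.86 ± 1.32 (SD, n = 4) in OVSAHO. Its relatives in the same regulatory group fell as well, CCN1 by 2.34 and ANKRD1 by 2.07. CCND1, which encodes cyclin D1 (chromosome 11, 69641087 to 69654474), fell by 1.79 (SE 0.10, limma adjusted p = 6.3e-13) and passed the test in each line, from 107 ± 3.46 (SD, n = 2) to 7.41 ± 1.96 (SD, n = 3) in OVCAR4. The growth-factor-induced transcription factor gene EGR1 fell by 2.10, the secreted glycoprotein gene FSTL1 by 2.07, and the fibrillar collagen-associated gene COL12A1 by 1.72.

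On the other side, the taurine transporter gene SLC6A6 (chromosome 3, 14402576 to 14489349) rose in each line and on average by 1.80 (SE 0.07, limma adjusted p = 1.2e-15). It went from 9.15 ± 2.00 (SD, n = 4) to 43.5 ± 4.64 scaled TPM (SD, n = 5) in COV362 and from 4.28 ± 0.777 (SD, n = 4) to 7.40 ± 0.971 (SD, n = 4) in OVSAHO. The secretoglobin gene SCGB2A1 had the largest mean rise, 2.60, most of it in OVCAR4, where it went from 3.74 ± 2.96 (SD, n = 2) to 318 ± 28.3 (SD, n = 3). TXNIP, a glucose-responsive inhibitor of thioredoxin, rose by 2.17. CYP1A1, a cytochrome P450 gene induced through the aryl hydrocarbon receptor, rose by 2.01 and passed in each line. Smaller mean rises were those of the matrix protease gene MMP7 (1.82), the ubiquitin ligase gene FBXO32 (1.74), the pluripotency factor gene POU5F1 (1.70, a gene with close pseudogene copies) and MUC16 (1.66), which encodes the CA-125 antigen. The other genes named by the rule for this comparison were PPFIA4, CHRD, SEMA5B and LINC00511 among the rises (1.75 to 1.87) and CLDN16, KCNIP1, PDPN, MEST and H2AC14 among the falls (-1.75 to -1.94).

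In all, 9188 of 16611 tested genes passed limma's test for the mean of the 4 lines at an adjusted p of 0.05, of which 5555 were higher and 3633 lower in spheroids. A change of at least a log2 value of 1 was reached by 197 of the higher and 151 of the lower genes. The split of directions depended on the scaling of the libraries. With TPM as deposited the median of all genes shifted by 0.20 (0.42 in COV362, 0.10 in Kuramochi, 0.05 in OVCAR4 and 0.18 in OVSAHO) and 7837 genes were higher against 1731 lower, and with quantile normalization 3833 were higher against 4122 lower. The main scaling left a median of 0.07.

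Among the 21 measured YAP/TEAD targets, 14 fell, 3 rose and 4 did not pass, with a mean log2 change of -0.75 over the list (camera adjusted p = 2.8e-07). Besides CCN1, CCN2 and ANKRD1, the members with the smallest p were the falls of CRIM1 (-0.77), LATS2 (-0.59) and AXL (-0.92). Of the 15 measured actin and SRF-regulated cytoskeleton genes 13 fell and none rose, with a list mean of -0.61 (camera adjusted p = 6.0e-09), as in the tropomyosin genes TPM1 (-1.15) and TPM4 (-0.84) and the calponin genes CNN2 (-0.68) and CNN3 (-0.61). Integrins and focal adhesion genes fell in 12 of 18 cases and rose in 1, with a mean of -0.29 (camera adjusted p = 4.4e-05), among them FLNA (-0.60), TLN1 (-0.60) and ITGAV (-0.51), but with adjusted p = 0.113 with an estimated correlation. Keratins fell in 7 of 12 cases with no rise, led by KRT18 (-1.10), KRT8 (-0.86) and KRT7 (-0.98), the list at -0.44 (camera adjusted p = 0.00021, adjusted p = 0.113 with an estimated correlation). Collagens, laminins and matrix glycoproteins went both ways, 9 higher and 11 lower of 29, as in COL17A1 (1.19), COL5A2 (0.65) and TNC (-1.46), and the list did not pass (-0.12, camera adjusted p = 0.139). The matrix glycoprotein list was lower in Kuramochi (-0.56, camera adjusted p = 0.0036) and OVSAHO (-0.59, 2.4e-08) and at 0.39 in COV362 (0.0511). With an estimated correlation the camera adjusted p was 0.364, 0.0837 and 0.489 in these lines. In OVCAR4 none of these 5 lists passed camera.

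Camera compares a list with all other genes and assumes a preset correlation of 0.01 between list members. Of the 39 lists, 20 passed it, 4 higher and 16 lower. With the correlation estimated from the residuals, 3 of these calls held, those of the YAP/TEAD targets, the actin and SRF-regulated genes and the replication-dependent histones, each at an adjusted p = 0.0425. Fry, which asks whether a list's genes on balance moved one way without comparing them with other genes, called 32 lists, the 20 among them. Reassigned culture labels still gave a median of 11 lists called, so a camera call at the preset correlation is weak evidence by itself. Unless another count is given, as many members of a list passed in each direction in the mean of the lines when adjusted over the list alone as over all genes.

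**Figure D2:**
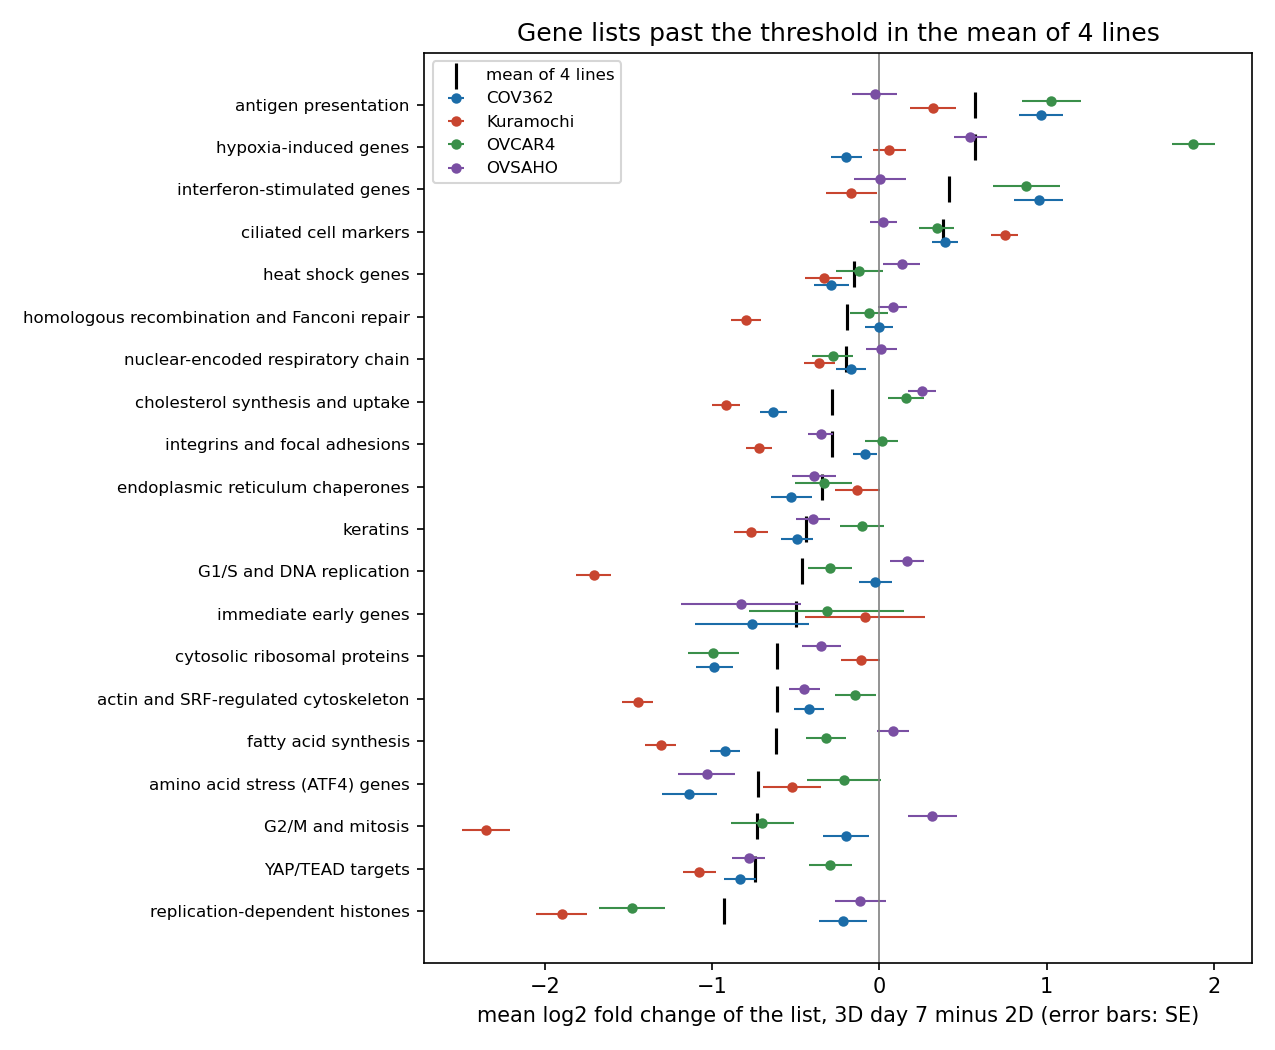
Mean log2 change, spheroids of day 7 minus monolayers, of the 20 gene lists that passed camera in the mean of the lines. Each list has 1 point per line and 1 for the mean of the 4 lines. The G2/M and mitosis list lay at -2.35 in Kuramochi against 0.32 in OVSAHO, and the hypoxia-induced list at 1.88 in OVCAR4 against -0.20 in COV362 (0.18 with TPM as deposited).

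Proliferation-associated transcripts were lower on average, with the weight of the change in Kuramochi, except that histone genes also fell strongly in OVCAR4. All 26 genes of the G2/M and mitosis list fell in the mean of the lines, with a list mean of -0.73 (camera adjusted p = 6.2e-16), as in CCNB2 (-0.73), UBE2C (-1.06) and AURKA (-0.79). In the G1/S and DNA replication list 22 of 25 fell, with a mean of -0.46 (camera adjusted p = 9.0e-11), among them CDT1 (-0.86), TYMS (-0.84) and MCM3 (-0.36). With an estimated correlation both lists had adjusted p = 0.113. Replication-dependent histone genes, which are transcribed in S phase and share reads between near-identical copies, fell in 37 of 42 cases (39 adjusted over the list alone), with a mean of -0.93 (camera adjusted p = 3.7e-20) and H1-5 (-1.60) and H2AC16 (-1.61) in front. Per line the histone list lay at -1.90 in Kuramochi, with 33 genes lower, and at -1.48 in OVCAR4, with 37 lower. With an estimated correlation the camera adjusted p was 0.0268 and 0.0982 in these lines. The histone list lay at -0.22 in COV362 and -0.11 in OVSAHO. Homologous recombination and Fanconi repair genes fell in 10 of 20 cases and rose in 2, with a mean of -0.20 (camera adjusted p = 0.0016, adjusted p = 0.295 with an estimated correlation), among them CHEK1 (-0.58) and BRCA1 (-0.41). The change in these lists differed between lines (limma adjusted p of 8.5e-11 for G2/M, 8.5e-11 for G1/S, 2.4e-08 for histones and 1.4e-06 for repair).

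Per line, the G2/M list fell by 2.35 in Kuramochi, where all 26 genes fell (camera adjusted p = 1.0e-28, 0.0277 with an estimated correlation), and by 0.70 in OVCAR4, where 16 fell (18 adjusted over the list alone; camera adjusted p = 8.6e-07, adjusted p = 0.715 with an estimated correlation). The proliferation marker MKI67 went from 26.9 ± 6.09 (SD, n = 4) to 1.93 ± 0.494 scaled TPM (SD, n = 4) in Kuramochi spheroids, a log2 change of -3.23 (limma adjusted p = 3.1e-11). It was 66.1 ± 11.6 (SD, n = 4) and 65.6 ± 6.04 (SD, n = 5) in COV362, and its log2 changes of 0.00 there, -0.45 in OVCAR4 and 0.64 in OVSAHO did not pass. In COV362 the G2/M list lay at -0.20 (camera adjusted p = 0.0036, adjusted p = 0.520 with an estimated correlation), but at 0.23 with TPM as deposited. In OVSAHO it lay at 0.32 (2.4e-05, adjusted p = 0.545 with an estimated correlation), and without replicate 2 of the OVSAHO monolayers at 0.06 with an adjusted p of 0.559.

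Hypoxia-induced genes rose in 22 of 28 cases in the mean of the lines (23 higher and 1 lower adjusted over the list alone), with a list mean of 0.57 (camera adjusted p = 5.3e-07, adjusted p = 0.113 with an estimated correlation). The change was concentrated in OVCAR4, at 1.88 with 25 genes higher, which held with an estimated correlation (adjusted p = 0.0299), and OVSAHO, at 0.54 with 14 higher (17 adjusted over the list alone; adjusted p = 0.0795 with an estimated correlation), and differed between lines (limma adjusted p = 8.5e-11). NDRG1, a stress-responsive gene, went from 43.7 ± 3.77 (SD, n = 2) to 1155 ± 304 scaled TPM (SD, n = 3) in OVCAR4. PFKFB4, which encodes a regulator of glycolytic flux, rose by 3.33 in OVCAR4 and 2.29 in OVSAHO. CA9, a carbonic anhydrase gene and hypoxia marker, went from 1.70 ± 1.83 (SD, n = 4) to 11.8 ± 4.95 (SD, n = 4) in OVSAHO (limma adjusted p = 2.3e-05). In COV362 the hypoxia list lay at -0.20 (camera adjusted p = 0.0216, adjusted p = 0.459 with an estimated correlation), with 4 genes higher and 8 lower (4 and 9 adjusted over the list alone), and at 0.18 with TPM as deposited. In Kuramochi it was at 0.06 and did not pass.

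Glycolytic enzyme genes rose in 9 of 16 cases and fell in 2, as in ENO2 (1.36) and HK1 (0.44), but the list did not pass in the mean of the lines (0.24, camera adjusted p = 0.160). Its change differed between lines (limma adjusted p = 6.4e-09), at 0.91 in OVCAR4, 0.53 in OVSAHO, -0.06 in COV362 and -0.42 in Kuramochi. Lipid synthesis genes fell in the mean of the lines. Of the 10 fatty acid synthesis genes 9 fell, with a mean of -0.62 (camera adjusted p = 7.3e-07, adjusted p = 0.0556 with an estimated correlation), and of the 24 cholesterol synthesis and uptake genes 16 fell and 1 rose, with a mean of -0.28 (7.4e-06, adjusted p = 0.171 with an estimated correlation). SCD, the stearoyl-CoA desaturase gene, went from 459 ± 142 (SD, n = 4) to 65.8 ± 12.3 scaled TPM (SD, n = 5) in COV362 and from 112 ± 27.2 (SD, n = 4) to 11.8 ± 1.75 (SD, n = 4) in Kuramochi. It was 430 ± 3.00 (SD, n = 2) against 663 ± 64.0 (SD, n = 3) in OVCAR4, which did not pass. The cholesterol list fell by 0.63 in COV362 and 0.92 in Kuramochi, with camera adjusted p = 0.0401 and 0.0341 with an estimated correlation. In OVCAR4 it was at 0.16 and did not pass. In OVSAHO it was at 0.26 with 8 genes higher and 0 lower (camera adjusted p = 2.2e-05, 0.226 with an estimated correlation). The change differed between lines (limma adjusted p = 2.7e-09).

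Cytosolic ribosomal protein genes fell in 39 of 40 cases with none higher, by 0.61 on average (camera adjusted p = 6.6e-20, adjusted p = 0.113 with an estimated correlation). RPLP0 (-0.80) and RPSA (-0.76) were among them, and RPLP0 passed in each line, from 1818 ± 115 (SD, n = 4) to 914 ± 110 scaled TPM (SD, n = 5) in COV362. Per line the list lay at -0.99 in COV362 (adjusted p = 0.0412 with an estimated correlation), -0.99 in OVCAR4 (0.363), -0.35 in OVSAHO (0.384) and -0.11 in Kuramochi, where it did not pass, and the lines differed (limma adjusted p = 3.4e-05). Amino acid stress (ATF4) genes fell in 19 of 21 cases and rose in 1, by 0.73 on average (camera adjusted p = 7.7e-10, adjusted p = 0.171 with an estimated correlation). The asparagine synthetase gene ASNS (-1.64), the one-carbon enzyme genes MTHFD2 (-1.24) and SHMT2 (-1.19), and PHGDH (-1.14), which encodes the first enzyme of serine synthesis, were among them. Endoplasmic reticulum chaperones fell in 15 of 20 cases and rose in 1, with a mean of -0.34 (camera adjusted p = 1.4e-05, adjusted p = 0.352 with an estimated correlation), as in HSPA5 (-0.72) and PDIA6 (-0.56).

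Immediate early genes fell in 7 of 23 cases with a mean of -0.50 (camera adjusted p = 0.0058, adjusted p = 0.604 with an estimated correlation), with EGR1 and MYC (-1.06) in front. FOS fell by 1.63 in the mean of the lines (limma adjusted p = 0.0056) and passed in no single line. Heat shock genes fell in 8 of 16 cases and rose in 3, with a mean of -0.15 (camera adjusted p = 0.0223, adjusted p = 0.504 with an estimated correlation), and the mean was 0.02 with TPM as deposited, where the list did not pass. HSPD1 (-0.74) and HSPA8 (-0.63) were among the falls. The scores of COV362 monolayers stood in 2 pairs, 0.46 and 0.45 in replicates 1 and 4 and -0.05 and -0.01 in 2 and 3. COV362 spheroids lay at -0.20 to 0.12, and without monolayer replicates 1 and 4 of COV362 the list did not pass (-0.09, camera adjusted p = 0.0726). In Kuramochi monolayers the scores were 0.23 and 0.18 in replicates 1 and 4 and -0.14 and -0.05 in 2 and 3. Kuramochi spheroids lay at -0.36 to -0.21. Nuclear-encoded respiratory chain genes fell in 18 of 29 cases (19 adjusted over the list alone) and rose in 1, with a mean of -0.20 (camera adjusted p = 8.4e-05, adjusted p = 0.311 with an estimated correlation), as in ATP5F1B (-0.47), and did not pass after quantile normalization. The mitochondrially encoded respiratory chain genes had a mean of 0.28 and did not pass (camera adjusted p = 0.624), with 1 of 13 higher, MT-ND5 (0.76), and none adjusted over the list alone. Metallothioneins fell in 5 of 8 cases, as in MT2A (-0.91), and the list did not pass (-0.37, camera adjusted p = 0.0517). Its scores in COV362 monolayers were 1.39 and 1.24 in replicates 1 and 4 but 0.19 and 0.27 in the others. It passed when any of 8 single libraries was left out, with an adjusted p of 0.0252 without replicate 3 of the Kuramochi monolayers.

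Of 28 interferon-stimulated genes 21 rose and none fell, with a mean of 0.42 (camera adjusted p = 0.00043, adjusted p = 0.443 with an estimated correlation), as in STAT2 (0.78) and IFI44 (0.63). Of 17 antigen presentation genes 13 rose (14 adjusted over the list alone) and none fell, with a mean of 0.57 (camera adjusted p = 0.00016, adjusted p = 0.295 with an estimated correlation), as in NLRC5 (1.06), which encodes a transactivator of class I genes, CIITA (0.87) and HLA-B (1.30), a gene with close relatives that share reads. HLA-B went from 61.8 ± 3.36 (SD, n = 2) to 560 ± 127 scaled TPM (SD, n = 3) in OVCAR4. Both lists differed between lines (limma adjusted p of 3.7e-05 and 4.4e-05). The interferon list lay at 0.95 in COV362, 0.88 in OVCAR4, -0.17 in Kuramochi and 0.00 in OVSAHO, and the antigen presentation list at 0.97, 1.03, 0.32 and -0.03. In COV362 and OVCAR4 both passed camera, with adjusted p of 0.177 for either list in COV362 and of 0.715 and 0.696 in OVCAR4 with an estimated correlation. In COV362 monolayers the interferon scores were 0.78 and 0.82 in replicates 1 and 4 but 1.45 and 1.48 in 2 and 3. COV362 spheroids lay at 1.84 to 2.36. The antigen presentation scores were 0.29 and 0.30 against 0.80 and 0.80, with spheroids at 1.45 to 1.62. Spheroids were above both pairs, but the size of the rise in COV362 depended on the pair. NF-kB targets and inflammatory cytokines went both ways, 5 higher and 8 lower of 19, and did not pass (-0.29, camera adjusted p = 0.139). Among them the chemokine genes CXCL1 and CCL2 fell by 1.34 and 1.49 and BIRC3 rose by 0.84.

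PAX8, the lineage transcription factor gene of the Mullerian epithelium, rose by 0.76 (SE 0.08, limma adjusted p = 2.2e-08), for example from 346 ± 27.5 (SD, n = 4) to 657 ± 160 scaled TPM (SD, n = 4) in Kuramochi, and did not pass in OVSAHO (0.26). MUC1 rose by 1.61. MUC16 went from 36.0 ± 15.2 (SD, n = 2) to 168 ± 38.5 (SD, n = 3) in OVCAR4 and did not pass in OVSAHO (1.12, limma adjusted p = 0.0688). WT1 had a mean log2 change of -0.37 (limma adjusted p = 0.0393), a call that was lost in 14 of the fits that left out 1 library (adjusted p = 0.0993 without replicate 1 of the OVCAR4 monolayers), and it fell by 1.13 in Kuramochi. The serous ovarian carcinoma marker list as a whole, with 8 higher and 5 lower of 18, did not pass (0.18, camera adjusted p = 0.594). Ciliated cell markers rose in 6 of 9 cases (7 adjusted over the list alone), with CAPS (0.94) and TPPP3 (0.77), and a list mean of 0.38 (camera adjusted p = 0.0435, adjusted p = 0.163 with an estimated correlation). That call was lost in 5 of the fits that left out 1 library, with adjusted p of 0.0531 without OVCAR4 monolayer replicate 1, 0.0515 without OVSAHO monolayer replicate 2, 0.0535 without COV362 spheroid replicate 3, and 0.0537 and 0.0540 without Kuramochi spheroid replicates 1 and 2.

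The remaining lists did not pass in the mean of the lines. Epithelial junction genes had 8 higher and 6 lower of 22, as in ELF3 (0.99) and CLDN3 (0.48) against DSG2 (-0.27) (list mean 0.14, camera adjusted p = 0.852). Mesenchymal genes had 4 higher and 2 lower of 12 (camera adjusted p = 0.852), with a mean of 0.06 and a direction of the test upward against a median of -0.01. VIM, the vimentin gene, went from 19.6 ± 1.84 (SD, n = 2) to 228 ± 16.4 scaled TPM (SD, n = 3) in OVCAR4 and did not pass in the other lines. Stem cell markers had 7 higher and 4 lower of 17 (0.17, camera adjusted p = 0.682), with rises of ALDH1A1 (1.02) and LGR5 (0.90) and a fall of ALCAM (-0.80). For p53 targets the counts were 6 and 3 of 16 (0.13, camera adjusted p = 0.606), with CDKN1A, the p21 gene, at 0.91. ABC drug transporters had 4 higher and 1 lower of 6 (0.29, 0.160), with ABCC6 at 0.87. TGF-beta targets had 4 and 3 of 12 (0.16, camera adjusted p = 0.672), with ID2 at 0.94. Lysosome and autophagy genes had 6 higher and 3 lower of 19 (6 and 2 adjusted over the list alone), with CTSS at 0.92. The list mean was 0.13 (camera adjusted p = 0.530). In OVSAHO the list was lower (-0.30, camera adjusted p = 2.4e-05, 0.184 with an estimated correlation). In Kuramochi it was higher (0.32, camera adjusted p = 0.0280, 0.486 with an estimated correlation). Matrix proteases and inhibitors had 4 and 4 of 12 (camera adjusted p = 0.672), with a mean of 0.02 against a median of -0.01 and a downward direction of the test. TIMP3, a metalloproteinase inhibitor gene of this list, fell by 1.29 and passed in each line. Circadian clock genes had 8 and 1 of 15 (0.27, camera adjusted p = 0.139), with BHLHE41 at 1.37. Nuclear-retained long RNAs had 3 and 0 of 4 (0.75, camera adjusted p = 0.0968), with NEAT1 at 1.16, KCNQ1OT1 at 0.91 and MALAT1 at 0.86. In every line the highest list score at day 7 was that of replicate 1, whose title did not end in 7days (1.28 in COV362 against 0.40 at most in the other day 7 libraries), and without these libraries the list mean was 0.54.

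Lists of markers of other cell types did not pass camera, although single genes on them did pass limma's test. Fibroblast markers had 2 higher of 4 measured (0.11, camera adjusted p = 0.624), mesothelial markers 2 lower of 3 (-0.48, 0.139; UPK3B at -1.24), and leukocyte and endothelial markers 3 higher and 2 lower of 6 (-0.06, 0.830; CDH5 at -0.74). Of the 8, 7 and 12 genes on these lists the others were below the filter.

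**Figure D3:**
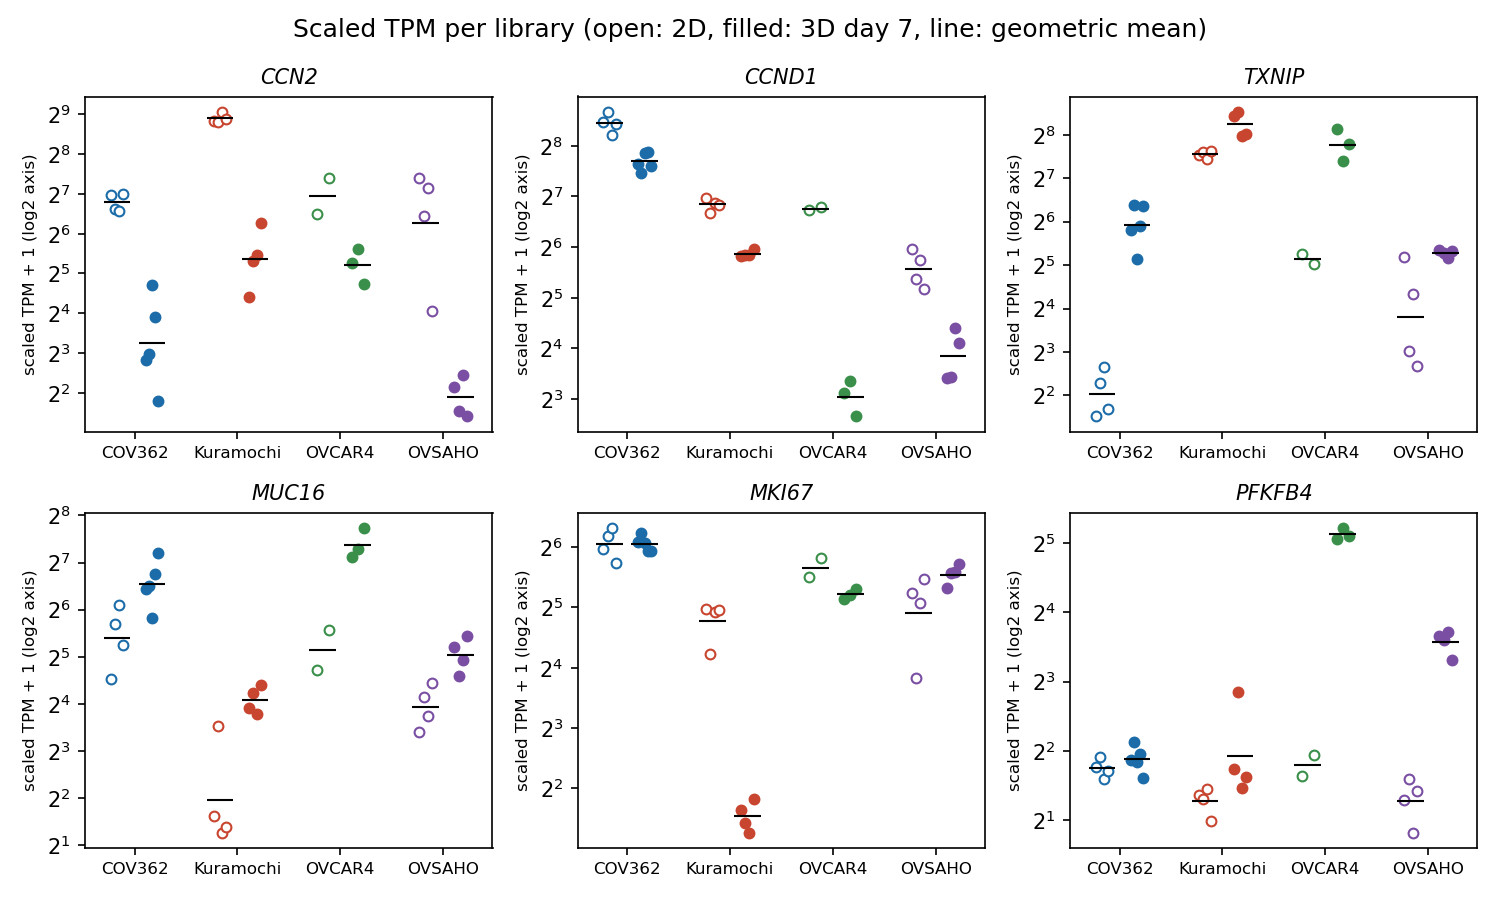
Scaled TPM of CCN2, CCND1, TXNIP, MUC16, MKI67 and PFKFB4 in each library on a log axis, monolayers beside day 7 spheroids of each line, with the group mean. CCND1 lay at 107 ± 3.46 (SD, n = 2) in OVCAR4 monolayers and 7.41 ± 1.96 (SD, n = 3) in spheroids, and MKI67 at 26.9 ± 6.09 (SD, n = 4) and 1.93 ± 0.494 (SD, n = 4) in Kuramochi.

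In COV362, the cardiac actin gene ACTC1 went from 5.29 ± 0.912 (SD, n = 4) to 59.1 ± 9.01 scaled TPM (SD, n = 5), the Wnt antagonist gene SFRP5 from 2.40 ± 1.05 to 41.5 ± 15.6, and MMP7 from 6.63 ± 2.56 to 110 ± 27.4 (same group sizes). The imprinted long RNA MEG3 rose by 3.57 and TXNIP by 3.88. SULT1E1, the estrogen sulfotransferase gene, fell from 23.0 ± 6.12 (SD, n = 4) to 0.629 ± 0.511 (SD, n = 5), and SPOCK2, KRT4 and CCN2 fell by 3.73, 3.33 and 3.55, with ANKRD1 between them. In all 5153 genes passed limma's test, 3350 higher and 1803 lower (2331 without monolayer replicates 1 and 4 and 6134 without 2 and 3, which differed from each other in 1550 genes), but 8956 and 470 with TPM as deposited and 2253 and 2132 after quantile normalization.

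In Kuramochi, ACTA2, the smooth muscle actin gene, went from 73.4 ± 60.7 (SD, n = 4) to 1.36 ± 0.329 scaled TPM (SD, n = 4), and SULF1 fell by 3.85. The histone genes H3C4 and H3C14 fell by 4.28 and 4.27. Among the rises, CCN3 went from 1.32 ± 0.272 (SD, n = 4) to 29.1 ± 7.99 (SD, n = 4) and PDK4, a kinase gene that limits pyruvate oxidation, from 3.52 ± 1.78 to 48.1 ± 8.07 (same group sizes), and LEFTY2, PTGDS and ZDHHC11B (a gene with a near-identical copy) rose by 3.36, 3.17 and 3.22. In all 7433 genes passed, 4135 higher and 3298 lower. On principal component 5 Kuramochi monolayers stood at 0.88 and 2.91 in replicates 1 and 4 but at -25.8 and -30.9 in 2 and 3. Fits without either of these pairs were not made.

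In OVCAR4, which had 2 monolayer and 3 spheroid libraries, 6093 genes passed, 3590 higher and 2503 lower (2343 and 3002 after quantile normalization). Apart from SCGB2A1 and NDRG1, the synuclein gene SNCB went from 4.73 ± 1.17 (SD, n = 2) to 151 ± 31.9 scaled TPM (SD, n = 3), and PPFIA4 and CHRD rose by 4.67 and 4.93. FAT3, an atypical cadherin gene, fell from 47.9 ± 17.7 (SD, n = 2) to 1.89 ± 0.665 (SD, n = 3), CCND1 by 3.71, AFAP1L2 by 3.21, RDH10 by 3.12 and TFPI2 by 2.98. Without replicate 1 of the OVCAR4 monolayers 3895 genes passed.

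OVSAHO changed least by this count, with 1643 genes, 639 higher and 1004 lower (1958 and 320 with TPM as deposited). The calcium-binding protein gene CALB1 went from 2.96 ± 2.77 (SD, n = 4) to 62.6 ± 21.9 scaled TPM (SD, n = 4), and SAMD11, CA9 and PFKFB4 rose by 2.30, 2.42 and 2.29. TNC, the tenascin C gene, fell from 40.1 ± 13.1 (SD, n = 4) to 4.51 ± 0.812 (SD, n = 4), RBP2 by 2.87, EGR1 by 3.54, CCN1 by 2.95 and CCN2 by 4.38. The somatostatin gene SST rose by 2.42 (limma adjusted p = 0.0203), a call lost without any of 3 libraries, the adjusted p being 0.107 without replicate 3 of the OVSAHO monolayers. Without that library 882 genes passed in this line.

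The culture effect differed between lines for 8782 genes (limma moderated F test, adjusted p under 0.05). Some genes went in opposite directions. TSPAN12, a tetraspanin gene, rose by 2.19 in OVCAR4 and fell by 1.35 in COV362 and by 0.59 in Kuramochi (difference between lines, limma adjusted p = 5.0e-12). CPT1A, which encodes the enzyme that admits long-chain fatty acids to mitochondria, rose by 1.69 in Kuramochi and 0.70 in COV362 and fell by 1.29 in OVCAR4. EGLN3, an oxygen-sensing hydroxylase gene, rose by 3.06 in OVCAR4 and fell by 0.84 in COV362, ARFGEF3 rose by 1.95 and fell by 0.37 in the same lines, and TNNT2 fell by 2.23 in Kuramochi and rose by 0.78 in OVCAR4. For H4C9, B4GALNT2 and LHX9 the second direction was lost when 1 library was left out, with adjusted p of 0.0719, 0.203 and 0.149. At least 2 lines had calls of opposite sign for 1251 genes.

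Shared calls were above the number that independent lists would give. In all 4 lines 61 genes were called higher and 77 lower, where independent lists of these sizes would share 6.93 and 3.26. Across genes, the log2 changes of the lines correlated with Pearson's r between 0.13 (OVCAR4 with OVSAHO) and 0.39 (Kuramochi with OVCAR4), genes not being independent replicates. Kuramochi and OVCAR4 shared 1618 higher and 1274 lower calls (894 and 497 for independent lists) and had 412 calls of opposite sign (1336 for independent lists). OVCAR4 and OVSAHO shared 218 higher and 237 lower calls (138 and 151) and had 304 of opposite sign (313).

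**Figure D4:**
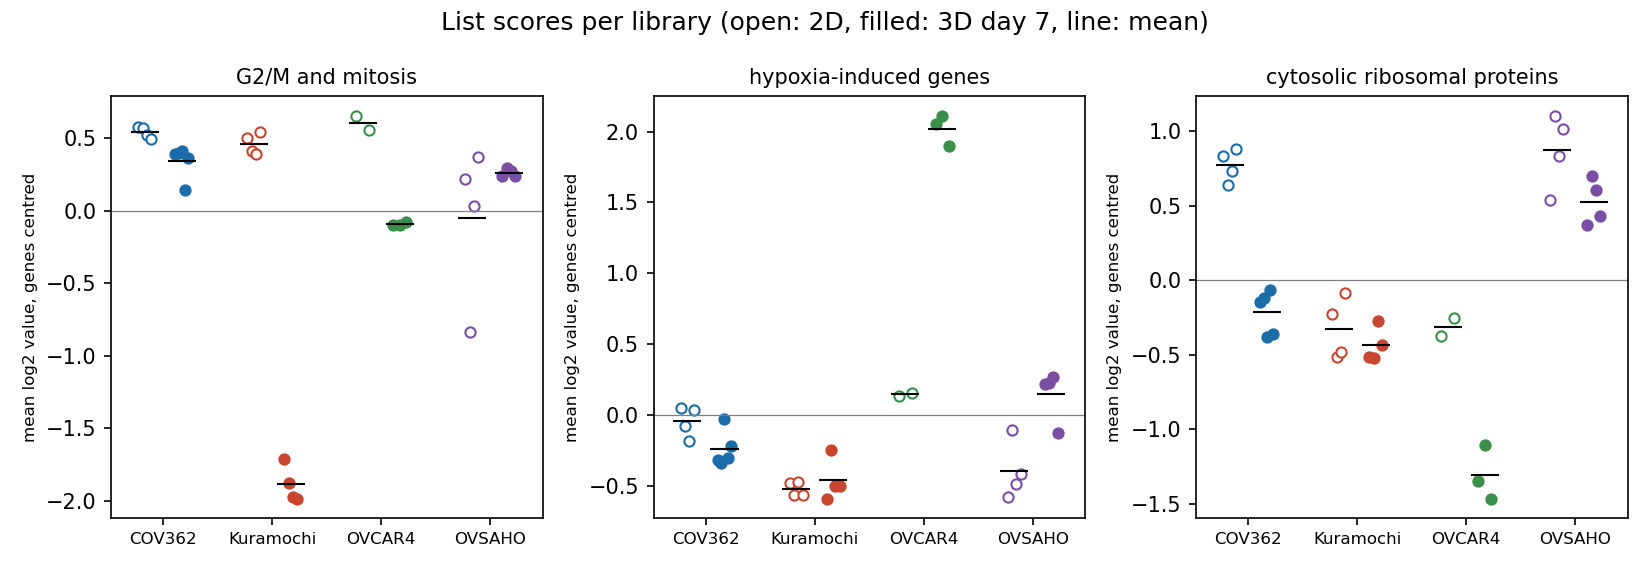
Mean centred log2 value of the G2/M and mitosis, hypoxia-induced and cytosolic ribosomal protein lists in each monolayer and day 7 spheroid library, by line. The Kuramochi spheroids lay between -1.71 and -1.99 on the G2/M list, and their monolayers between 0.39 and 0.55.

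Before any spheroid was formed the lines differed in most genes, with 14551 of 16611 passing limma's moderated F test between the 4 monolayer means. COV362 monolayers stood out by SHISA3, COL9A1, COL1A2 and the antisense long RNA AFAP1-AS1, with SHISA3 at 197 ± 73.4 scaled TPM (SD, n = 4) and COL1A2 at 70.2 ± 7.41. Kuramochi stood out by the dipeptidyl peptidase gene DPP4, at 86.4 ± 13.6 (SD, n = 4) against at most 0.489 on average in the other lines, and by CCDC144NL-AS1, RNF212 and COL3A1. OVCAR4 stood out by S100A14 at 269 ± 26.1 (SD, n = 2), LCP1 at 96.7 ± 0.363, H3C8 and the epithelial trafficking gene RAB25 at 52.2 ± 3.64, and OVSAHO by the imprinted long RNA H19 at 935 ± 432 (SD, n = 4), SST at 635 ± 550, and the cancer-testis genes CT45A10 and MAGEA1 (126 ± 18.3 and 65.5 ± 1.66), which belong to families of close copies. The lines were grown in different media per the labels, so line and medium cannot be told apart.

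Days 3 and 10 had 1 library in each of 3 lines, lines standing as the only replicates of these days, and were compared with the 16 libraries of day 7. Of the 16 residual degrees of freedom, 12 came from the spread between day 7 libraries of the same line. The p-values therefore measure mostly that spread, and only in small part how far the lines agreed. In the comparison 3D day 10 against day 7, 1722 of 16652 genes passed limma's test, 889 higher and 833 lower at day 10. The nuclear long RNAs MALAT1 and NEAT1 had log2 changes of 1.42 and 1.25 (limma adjusted p of 0.0263 and 0.0384), and the alpha globin gene HBA2, which has a near-identical neighbour, 4.28 (0.0228). Lower at day 10 were the interferon-induced IFI27 (-1.17), the phosphatase gene DUSP2 (-1.17), the histone gene H3C7 (-1.15), DOK7, ANTKMT (-1.26) and SNHG9 (-1.28). Further named genes were COMMD3-BMI1 (2.98), RPL17-C18orf32 (1.65), INMT-MINDY4 (1.22) and ST20-MTHFS (-1.14), which are read-through loci, and BCYRN1 (1.89), NPIPA9 (1.24) and SLX1A (-1.58), which have close copies, so that their values are uncertain. The count rested on single libraries: it was 93 without the OVCAR4 day 10 library, 521 without that of OVSAHO, 586 without that of Kuramochi, 1029 without OVCAR4 day 7 replicate 3 and 2859 without OVCAR4 day 7 replicate 1. It was 0 (1662 at an unadjusted p under 0.05) when day 7 was represented only by the 4 libraries whose titles did not end in 7days, where MALAT1 was at 0.69, and MALAT1, NEAT1 and HBA2 each lost their call without any of the day 10 libraries.

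Between day 3 and day 7 no gene passed limma's test, and 1822 had an unadjusted p under 0.05. Among the genes with the smallest p-values, none of which passed, were the metallothionein gene MT1F (log2 change 1.17 at day 3, limma adjusted p = 0.354), SS18L2 (-0.67), the ecto-nucleotidase gene NT5E (0.77) and SKAP2 (0.49). In the simulated data of this design 38.8, 97.0 and 98.5% of genes changed by a log2 value of 0.5, 1 and 2 were recovered. The simulation gave each line the same change and held no difference between sets of libraries, so recovery in the data is unknown. No title of the day 3 libraries ends in 7days, so a difference between libraries by title form also enters this comparison.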

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

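None of the tests in this part was chosen only after its own result was seen, but the 3 patterns they address had been noticed in the same data beforehand.

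The size of the culture effect differed between lines in 33 of the 39 gene lists, by a test of the difference itself. The distance between the line with the highest and the line with the lowest mean log2 change was 2.67 for G2/M and mitosis genes, 1.87 for G1/S and DNA replication genes and 1.79 for replication-dependent histones, with Kuramochi lowest in each. It was 2.07 for hypoxia-induced genes and 1.33 for glycolytic enzymes, with OVCAR4 highest. In lipid metabolism it was 1.39 for fatty acid synthesis and 1.17 for cholesterol synthesis and uptake. For translation and stress lists it was 0.88 for cytosolic ribosomal proteins, 0.93 for amino acid stress genes, 0.47 for heat shock genes and 1.21 for metallothioneins. Among the adhesion lists it was 0.78 for YAP/TEAD targets, 1.30 for actin and SRF-regulated genes, 0.74 for integrins and focal adhesions, 0.98 for collagens, laminins and matrix glycoproteins and 1.00 for matrix proteases and inhibitors. It was 0.56 for epithelial junctions, 0.83 for mesenchymal genes, 0.66 for keratins, 0.50 for serous carcinoma markers and 0.80 for stem cell markers. Interferon-stimulated genes had 1.12, antigen presentation genes 1.06, p53 targets 0.96, TGF-beta targets 0.89 and homologous recombination genes 0.88. Circadian clock genes had 0.97, ciliated cell markers 0.72, lysosome and autophagy genes 0.63, ABC drug transporters 0.60, nuclear-retained long RNAs 1.23, fibroblast markers 0.78 and leukocyte and endothelial markers 1.15.

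Single libraries lay far from the rest of their group in 13 of the 252 pairs of a group and a measure examined, the measures being list scores and library measures, where about 1 in 20, here 12.6, is the number that chance gives. The centred list score of replicate 2 of the OVSAHO monolayers for replication-dependent histones was -1.32 (nearest other library -0.37), and that of replicate 2 of the Kuramochi monolayers for mesenchymal genes was 0.26 (nearest 0.61). Among COV362 spheroids of day 7, replicate 5 stood at 0.14 for G2/M and mitosis genes (nearest 0.36), replicate 4 at 0.54 for NF-kB targets (nearest 0.07), and replicate 1 at -0.25 for p53 targets, -0.36 for ciliated cell markers and 1.28 for nuclear-retained long RNAs (nearest 0.40). Among Kuramochi spheroids, replicate 3 stood at 0.28 for collagens, laminins and matrix glycoproteins, and replicate 4 at -0.45 for antigen presentation genes and 0.17 for circadian clock genes. Among OVSAHO spheroids, replicate 1 stood at 0.012 for G1/S and DNA replication genes and -0.13 for hypoxia-induced genes, and replicate 2 at -0.093 for ciliated cell markers. The OVCAR4 spheroid library without a day, which entered no comparison of the report, had a mean correlation of 0.935 with OVCAR4 monolayers and at most 0.831 with those of another line.

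Transcripts of ribosomal protein genes were lower in spheroids by a mean log2 change of -0.61. None of the 10000 random lists matched on expression and transcript length fell as far (percentile 0, central 95% of their means -0.37 to -0.14), and none matched on expression and GC content did (percentile 0, -0.34 to -0.09), which argues against a trend with length or with GC content as the whole cause. These random lists had median changes of -0.25 and -0.22, so such trends may hold part of the fall. Length and GC content were not matched together. Ribosomal protein genes share regulation, which independent draws do not reproduce, so the percentiles overstate the contrast. Without the day 7 libraries whose titles do not end in 7days, the ribosomal protein list had a change of -0.57 (2 SE either way, -0.70 to -0.43). That argues against a difference between these sets of libraries as the cause. The dissociation of spheroids, which was not applied to monolayers, stays open because it follows the culture form exactly. With that reservation, lower expression of ribosomal protein genes in spheroids remains a hypothesis, found and tested on the same data.

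In Kuramochi the G2/M and mitosis list had a mean log2 change of -2.35 in spheroids. The smallest fall with TPM as deposited or quantile normalization was -2.29 (2 SE either way, -2.57 to -2.02), which argues against the scaling as the cause. In the single Kuramochi library of day 7 whose title does not end in 7days, with a spread taken from the other groups, the fall was -2.16 (-2.76 to -1.55), and in the other 3 it was -2.40, so both sets held the fall, the first in 1 library only. Cells of another kind were argued against by the 20 genes that stood out most in Kuramochi monolayers, whose median change was -0.33 (quartiles -1.08 to 0.19) where replacement of most cells would have lowered all of them by about as much as the list. A lower share of cycling cells in Kuramochi spheroids may account for the pattern. It stays a hypothesis, since no measure of growth other than RNA was available and the dissociation step stays open.

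Between day 10 and day 7, 1722 genes passed limma's test, but 12 of the 16 day 7 libraries have numbered titles ending in 7days, and the other 4 are titled more like those of days 3 and 10, except that the one of Kuramochi carries a number. Among the day 7 libraries alone, 2357 of 16250 genes differed between these sets, 1068 of them higher and 1289 lower. Against the 4 day 7 libraries alone, the day 10 change of the called genes had a median ratio of 0.697 to the change against all day 7 libraries (quartiles 0.573 to 0.835), and no gene passed the threshold in that smaller fit (1662 at an unadjusted p under 0.05). Age and the difference between these sets of libraries cannot be told apart for the called genes, because the ratio lay between the bounds of 0.5 and 0.8 set beforehand and shares its day 10 libraries with the comparison it is set against. HBA2 was listed at 109, 67.1 and 41.3 scaled TPM in the day 10 libraries of Kuramochi, OVCAR4 and OVSAHO, above the earlier spheroids of each line, and at 183 in the day 3 library of COV362 and 89.0 in day 7 replicate 1 of COV362, a line without a day 10 library, while single monolayers reached 236 in Kuramochi and 99.7 in OVCAR4 (scaled with the day 7 libraries).

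Other splits of the same libraries bear on chance. Of the 100 reassignments of culture labels within lines, 1, the real one, gave as many as 9188 genes in the mean of the lines, and the highest other gave 4567. For COV362 it was 1 of 100 (5153 genes, highest other 3116), for Kuramochi 1 of 35 (7433, highest other 1259) and for OVSAHO 1 of 35 (1643, highest other 53). Chance was excluded at 0.05 for these counts only if the libraries of a line are exchangeable. The labels do not show this, and the COV362 monolayers stood in 2 pairs. OVCAR4, with 2 monolayer libraries, was not examined in this way. The difference between lines was as large in 1 of 100 splits for genes (8782, highest other 2420) and 1 of 100 for lists (33, highest other 20). For the number of lists called in the mean of the lines chance was not excluded, since 8 of 100 splits gave as many as the real 20, the highest other 23. The median of the other splits was 11 lists, where that of the gene count was 0. The day 10 count was as large in 1 of 100 splits (1722, highest other 148). The libraries of a line were not exchangeable there, since no day 10 title ends in 7days and 2357 genes differed by title form within day 7. The highest other split kept the Kuramochi and OVSAHO day 10 libraries. For OVCAR4 it took day 7 replicate 1, whose title does not end in 7days. The day 10 splits therefore cannot tell age from title form. The day 3 count of 0 was reached in 100 of 100 (highest other 2), as any split must, so the splits cannot bear on it.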

How the results depend on the processing

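Alternatives were fixed before the data were examined, except the fits that separate day 7 libraries by whether their titles end in 7days and those without a pair of COV362 monolayers, which were chosen after seeing the data. Among 262 values of named genes, 251 kept their direction and their side of the threshold with TPM as deposited, 254 with quantile normalization, 255 with a pseudocount of 0.1, 254 without a filter and 262 with limma's array weights. Calls were lost for 34 of 241 values with the line from the cell line field, 9 of 220 with the replicate block, 3 of 21 with cell means of line and day, and 16 of 21 with day 7 taken only from titles not ending in 7days, which were all the named day 10 calls. Of 7680 values from fits that left out 1 library, 7590 did so, 76 lost their call and 14 gained it. Directions reversed for 3 values: SST in OVSAHO (-1.16) and ESRP1 in the mean of the lines (0.21) with the line taken from the cell line field, which places OVCAR4 spheroids among those of OVSAHO by construction, and DNAH5 in the mean of the lines with quantile normalization (-0.018), for which the cause was not tested.

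Counts that moved by more than 1.5 times were the following. With TPM as deposited 9426 genes passed in COV362, where the median of all genes shifted by 0.42, and 2806 for day 10. Of the 5153 COV362 calls 3817 were shared in direction and 1 was opposite, and in the mean of the lines 7285 of 9188 were shared and 0 opposite. Without the libraries with conflicting labels 4013 genes passed in OVCAR4, where a single spheroid library was left and the spread came from the other groups. Without replicates 1 and 4 of the COV362 monolayers 2331 genes passed in COV362, of which 2121 were shared in direction with the 5153 and 0 opposite, and the heat shock list (adjusted p = 0.0726) and ciliated cell markers (0.0536) lost their call. Without replicates 2 and 3 the count was 6134 and metallothioneins passed (0.0061), while WT1 (0.142) and MT-ND5 (0.0734) lost their call in the mean of the lines. These pairs differed in 1550 genes, and the other 2 ways of pairing the 4 libraries gave 0. Kuramochi monolayers stood in like pairs by number, for which no such fit was made. With the line from the cell line field the counts were 6041 in the mean of the lines, 2553 in COV362, 4868 in Kuramochi, 1079 in OVCAR4 and 3852 for the difference between lines, with 21 lists differing, because libraries of unlike lines then share a group. Limma's array weights gave 3293 in OVSAHO and 2814 for day 10, and no filter 1113 for day 10; the cause was not tested. With day 7 taken only from the libraries whose titles do not end in 7days, 0 genes passed in limma (1662 at an unadjusted p under 0.05) in a fit of 10 libraries. Camera with an estimated correlation called 3 of the 39 lists and fry 32, where the preset correlation called 20. With TPM as deposited 2 lists lost their call (heat shock genes and ciliated cell markers, adjusted p of 0.0551 and 0.0581) and 5 gained it. With quantile normalization 3 lost it (these 2 at 0.600 and 0.147, and the nuclear-encoded respiratory chain at 0.259) and 3 gained it.

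With the replicate number as a replicate block within each line, 6367 genes passed in the mean of the lines, 7303 in Kuramochi, 2485 in COV362, 2178 in OVCAR4, 745 in OVSAHO and 5839 for the difference between lines, in a fit with fewer libraries. The labels do not say that equal numbers mark a shared culture. The residuals of 11 pairs with the same number correlated at r between -0.14 and 0.28, with 3 over 0.1 and a median of 0.04 against -0.01 for pairs with different numbers, so the unblocked fit was kept. The 3 pairs over 0.1 were all of Kuramochi. Residuals of COV362 day 7 spheroid replicate 5 correlated at 0.44 and 0.40 with monolayer replicates 2 and 3, and at -0.42 with each of 1 and 4. Structure shared across culture forms was thus not all marked by equal numbers, and its cause was not tested.

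Leaving out each library in turn gave 8199 to 9284 genes in the mean of the lines, 3740 to 5472 in COV362 and 6607 to 7575 in Kuramochi. OVCAR4 had 3895 (without replicate 1 of its monolayers, which leaves a single monolayer library assumed to vary like the other groups) to 6215, and OVSAHO 882 (without replicate 3 of its monolayers) to 1859. The difference between lines had 7848 to 9004 genes, that between monolayers 14173 to 14554, the lists 19 to 21 and the list differences 32 to 34. Day 10 had 93 (without the OVCAR4 day 10 library) to 2859 (without OVCAR4 day 7 replicate 1), with 521, 586 and 1029 without the OVSAHO and Kuramochi day 10 libraries and OVCAR4 day 7 replicate 3. Day 3 had 0 in each fit. The unknown depth limits statements about genes near the filter of TPM 1.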

Other observations

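The adhesion-related changes had different weights in the lines. YAP/TEAD targets fell in Kuramochi by 1.08, in COV362 by 0.83 and in OVSAHO by 0.78, each past camera's threshold also with an estimated correlation (adjusted p of 0.0268, 0.0401 and 0.0211), whereas OVCAR4 had -0.29 and did not pass, and the lines differed (limma adjusted p = 0.0012). Actin and SRF-regulated genes fell by 1.44 in Kuramochi with all 15 genes lower, and were at -0.42 in COV362, -0.45 in OVSAHO and -0.14 in OVCAR4. TIMP3 fell to a like extent in each line, by 1.19 in COV362, 1.18 in Kuramochi, 1.53 in OVCAR4 and 1.25 in OVSAHO (difference between lines, limma adjusted p = 0.610). CXCL1 likewise had -1.28, -1.28, -1.25 and -1.53 (0.931), the OVCAR4 value not passing without replicate 1 of its monolayers (limma adjusted p = 0.234).

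Amino acid stress genes fell by 1.13 in COV362 and 1.03 in OVSAHO (camera adjusted p of 0.157 and 0.0837 with an estimated correlation) and were at -0.52 in Kuramochi and -0.21 in OVCAR4 (difference between lines, limma adjusted p = 0.0082). CDKN1A rose by 2.60 in OVCAR4 and by 1.31 in COV362 and was at -0.81 in Kuramochi (limma adjusted p = 0.0320 there, 0.0834 without replicate 1 of the Kuramochi monolayers), so the line whose proliferation transcripts fell furthest was not the one in which this cell cycle inhibitor gene rose. CCND1 fell furthest in OVCAR4.

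The OVCAR4 spheroid library without a day had list scores relative to the OVCAR4 monolayers of 2.59 for hypoxia-induced genes (1.91, 1.97 and 1.75 in the day 7 libraries), 1.34 for glycolytic enzymes, -0.98 for G2/M and mitosis genes (-0.71, -0.70 and -0.69 at day 7), -1.68 for replication-dependent histones and -0.90 for ribosomal proteins. It is a single library and no test was made. Its values were matched through a library name whose number differs from that of its title, and their name carries a mark of confluence.

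Tests in this part followed ideas that arose from the genes already seen, and each was written down before its own result was seen. The hypothesis tested first was that the translation machinery beyond the ribosomal proteins is lower in spheroids. All 12 genes examined, which were translation factor genes and also TPT1 and NAP1L1, fell in the mean of the lines, by -0.71 on average. EEF1B2 (-1.17), EEF1A1 (-0.82), EEF2 (-0.73) and PABPC1 (-0.73) were among them. Their mean lay at percentile 0.03 of random lists matched on expression (central 95% -0.51 to -0.05). These genes share regulation with the ribosomal proteins, whose fall had already been seen, and the random lists did not match on this. The test therefore cannot tell a wider fall of the translation machinery from that shared regulation. The dissociation, a step applied to spheroids alone, was not separable either.

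A further hypothesis was that targets of the aryl hydrocarbon receptor rise together with CYP1A1. Of 5 further targets 3 rose, among them CYP1B1 (0.77) and AHRR (0.61), and NQO1 fell (-0.37). Their mean of 0.28 lay at percentile 90.6 of matched random lists (central 95% -0.24 to 0.39), which left the question undecided.

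Another hypothesis, prompted by the falls of EGR1, MYC and CCND1, was that the transcriptional output of the ERK pathway is lower in spheroids. Of 7 other output genes 5 fell and 1 rose, with DUSP5 at -1.11, EPHA2 at -0.99 and SPRED3 at 0.28, and their mean of -0.38 lay at percentile 0.16 (central 95% -0.21 to 0.36). As a set these genes were lower than such lists. The lists were matched on expression alone and not on shared regulation, and the dissociation of spheroids was not separable. The test therefore cannot settle whether pathway output was lower. EPHA4, at 0.28, did not pass and no protein was measured.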
